A study of Homo sapiens with 6 samples.

How the data were processed

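Gene expression was measured on 6 oligonucleotide arrays, 1 per sample, in 3 samples of parental NCI-H1975 cells and 3 samples of WZR6 cells. NCI-H1975 is a human non-small cell lung cancer line that carries mutant EGFR. Per the labels, WZR6 is a clone of it isolated after growth in rising amounts of WZ4002, an EGFR kinase inhibitor, and cells of both groups were harvested during exponential growth in medium with 5% serum. Whether WZ4002 was in the medium at harvest is not given in the sources used here. The deposited table holds 1 intensity per probe set and array, on a linear scale, made with RMA per the submitters' processing notes. RMA subtracts background, quantile normalizes the probe values and summarizes them per probe set; its version and settings are not given in the sources used here. Intensities ran from 9.87 to 44567, and the median of the arrays lay between 163 and 170. The table carries no detection calls, so it does not say which probe sets were above background.

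The deposited intensities were converted to log2 with no pseudocount and were not normalized again. Of 22277 probe sets, 62 control probe sets were left out of the tests and 22215 were tested. The platform's annotation named 1 gene for 19064 probe sets, several genes for 1043 and was silent on 2108. Names came only from probe sets with 1 gene, and 19052 of these were matched by Entrez identifier to the RefSeq table of GRCh38.p14, with 0 symbols changed. Each of 11963 genes was represented by its own probe set with the highest mean over all 6 arrays; 4310 genes had more than 1 probe set of their own. No coordinates are given, because the build behind the annotation is not given in the sources used here.

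Groups were taken from the sample titles. WZR6 was compared with parental cells with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), once over probe sets and once over genes, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. Differences are log2 of WZR6 minus parental, and a fold is the ratio of geometric means. Errors of differences are standard errors of the moderated fit, and intervals have 95% confidence. The 27 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and beside it with a correlation estimated from the data and with fry. The lists, the tests, the rule for named genes and the alternatives below were fixed before the data were examined. The lists covered ERK feedback and ERK-induced transcripts, RAS-RAF-MEK-ERK components, receptor tyrosine kinases and their ligands, PI3K-AKT-mTOR components, the BCL2 family, epithelial and mesenchymal genes, cell cycle, interferon response, NF-kB and cytokines, antigen presentation, drug transport and metabolism, NRF2 targets, lung, neuroendocrine, squamous, leukocyte and fibroblast or endothelial markers, cholesterol synthesis, glycolysis and hypoxia, ATF4 and unfolded protein response, YAP-TEAD, TGF-beta and WNT targets, and housekeeping genes.

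The rule for named genes took the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap, 12 genes chosen for the study's question, and in each list up to 4 called members with the largest differences. This gave 127 measured genes. A gene with another probe set of its own called in the other direction was to be named as uncertain. Other members of the lists that appear in the text were chosen after their values were seen. Some of the chosen genes are not reported here.

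Alternatives were cyclic loess, median centring and quantile normalization of the arrays, filters on dim probe sets, a floor at the median of all values, an intensity trend with robust variance, the replicate number as a block, the mean of a gene's probe sets, leaving out probe sets of the types _x_at and _s_at, which can detect several transcripts, and leaving out each array in turn. The brightest probe set over all 6 arrays stood for a gene in every alternative that did not change that rule; an earlier version of the leave-one-out fits chose it again among 5 arrays, and this was changed after it was seen to switch the probe set of COL1A1. A list past the threshold neither in the reported fit nor in an alternative was counted as the same whatever the sign of its median. The model was tested on simulated data with the arrays' own spread. Only 100 genes or probe sets were changed by each amount, with independent normal noise. In the data far more genes, 5748, were called, so the shares below do not give the recovery in this comparison. In the gene-level fit, run on 11963 genes, 69 of 100 genes changed by 0.5 log2 and 93 of 100 genes changed by 1 log2 were called, and 6.36% of calls were false. In the probe set fit, run on 22215 probe sets, 55 of 100 and 81 of 100 were called, and 3.55% of calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays, 3 per group, limits the precision of every value. The labels do not say whether the triplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and 1 clone stands for all resistant cells.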

Results

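The transcriptome of NCI-H1975 lung cancer cells was profiled before and after the acquisition of resistance to WZ4002. The series names ERK signaling as a source of resistance to EGFR kinase inhibitors, and the comparison asks which transcripts differ between the drug-sensitive parental line and the resistant clone WZR6. Each group held 3 arrays, and n = 3 per group holds for every value below. Over 22215 probe sets, log2 intensities correlated across genes with r between 0.9978 and 0.9983 within a group and between 0.9815 and 0.9826 across groups, and 0 arrays were identical to another over all probe sets.

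The epithelial adhesion genes EPCAM and CDH1 were among the largest decreases in WZR6, and the matrix genes POSTN and COL4A5 were among the largest increases. The largest decrease was that of EPCAM, an epithelial adhesion molecule, from 12.43 ± 0.08 (SD) in parental cells to 6.17 ± 0.26 in WZR6, or 76.8-fold (95% interval 62.2 to 94.7). CDH1, which encodes E-cadherin, was 51.7-fold lower (46.0 to 58.1), and ESRP1, an epithelial splicing regulator, was 26.1-fold lower (20.8 to 32.7). The 10 largest decreases also held CP (ceruloplasmin, 51.5-fold), TMEM30B (42.9-fold), GPNMB (42.4-fold), PTGS2 (the inducible prostaglandin synthase COX-2, 40.6-fold), TCN1 (a vitamin B12 carrier, 27.8-fold), PCOLCE2 (22.5-fold) and IFITM1 (an interferon-induced membrane protein, 18.6-fold). The largest increase was that of POSTN, which encodes the matrix protein periostin, from 4.26 ± 0.09 to 11.29 ± 0.07, or 131-fold (118 to 145). BCHE (butyrylcholinesterase) rose 42.7-fold, OLR1 (a receptor for oxidized LDL) 34.8-fold, COL4A5 (a basement membrane collagen chain) 32.5-fold and INHBA (the activin A subunit) 20.2-fold. MEOX1, GAS1, GSTA1, L1CAM and TMPRSS3 completed the 10 largest increases, at 10.4-fold, 10.2-fold, 9.39-fold, 8.48-fold and 8.40-fold. Adjusted p-values of these 20 genes in limma lay at or below 6.89e-06.

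Across the array, 5748 of 11963 genes were called (48.0%), 2932 higher and 2816 lower in WZR6. Decreases made up 49.0% of these calls, 54.1% under cyclic loess and 42.2% under median centring, so the balance of all calls turned with the scaling. With a difference of at least 2-fold, 163 genes were higher and 409 lower, so that 71.5% of the larger changes were decreases. Over probe sets, 9131 of 22215 were called, 4807 higher and 4324 lower, of which 253 and 588 passed 2-fold. The groups did not overlap for 56.3% of genes, against 10% by chance for 3 arrays against 3. The dimmer group lay below the lower quartile of all log2 values, 5.27, for 99 of the 572 genes called at 2-fold or more, among them POSTN, BCHE, GAS1, CP, TMEM30B, PTGS2, ESRP1 and PCOLCE2, and background limits the folds of such genes. BCL2A1, CYP24A1, HLA-DPA1, ERBB3, MERTK and EGF, given below, also had a WZR6 mean below that quartile. POSTN was no longer called when _x_at and _s_at probe sets were left out, since its remaining probe set differed by 0.03, and GAS1 was no longer called with a floor at the median of all values.

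Negative regulators of ERK signaling were lower in WZR6 for 6 of 11 measured genes, and the other 5 were not called. DUSP6, the ERK-specific phosphatase, fell from 10.83 ± 0.10 (SD) to 8.83 ± 0.07, or 3.98-fold (3.56 to 4.45, adjusted p = 1.92e-06 in limma), and its 3 probe sets differed by -1.88 to -2.06. DUSP5, a nuclear ERK phosphatase, fell 1.99-fold, SPRY4 (a Sprouty inhibitor of receptor signaling) 1.57-fold and SPRED2 1.37-fold, although SPRY4 was not called with the floor and SPRED2 was not called as the mean of its probe sets. NF1, the RAS-inactivating neurofibromin, differed by 0.03 ± 0.09 (SE, adjusted p = 0.818), on a probe set whose parental mean, 4.47, lay below the lower quartile. The list as a whole had a median difference of -0.26 and was not called (camera adjusted p = 0.0786; 0.322 with an estimated correlation). It was called without _x_at and _s_at probe sets, with a median of -0.35 and an adjusted p of 0.0121; over its alternatives the adjusted p ranged from 0.0121 to 0.568.

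Among 19 ERK-induced transcripts 9 fell, 4 rose and 6 were not called, with no call for the list (adjusted p = 0.126; 0.0208 without _x_at and _s_at probe sets). HMGA2, a chromatin protein, fell 2.37-fold, the immediate early factor EGR1 2.16-fold, PLAUR, the urokinase receptor, 2.04-fold and the AP-1 subunit FOSL1 1.84-fold. FOSL1 lies in a run of 55 neighbouring genes whose median difference was -0.54. Of 19 components of the RAS-RAF-MEK-ERK cascade, 5 rose, 2 fell and 12 were not called. RPS6KA1, an ERK-activated kinase, rose by 0.88 ± 0.05 (SE) and the RAS-related RRAS2 by 0.75 ± 0.04, while the RAS exchange factor SOS1 fell by 0.58 ± 0.05 and the adaptor GRB2 by 0.46 ± 0.06. GRB2 lies in a run of 83 neighbouring genes with a median of -0.47. MAPK3, which encodes ERK1, differed by 0.09 ± 0.08 (adjusted p = 0.394).

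Receptor tyrosine kinases moved both ways, with 7 of 24 higher, 7 lower and 10 not called. EGFR, the drug's target, was 1.75-fold lower (1.57 to 1.96, adjusted p = 9.22e-05), within a run of 174 neighbouring genes whose median difference was -0.54. A second bright EGFR probe set differed by -0.45, 3 of the 6 were not called, and EGFR had no call from probe sets other than _x_at and _s_at. Its dimerization partner ERBB3 fell 7.78-fold, ERBB2 1.53-fold, the hepatocyte growth factor receptor MET 1.97-fold and the related MST1R 3.11-fold. The WZR6 mean of ERBB3 lay near background, at 4.62, and its call ended with the floor and without _x_at and _s_at probe sets. MERTK fell 3.81-fold, with the same loss under the floor and a change of sign without those probe sets. AXL, a receptor of the TAM family, was 1.46-fold higher. IGF1R is uncertain, since its main probe set rose by 0.58 while another of its own was called at -0.69.

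Ligands of these receptors fell for 8 of 15 measured genes, and 7 were not called (median -0.28, camera adjusted p = 0.0246; adjusted p = 0.248 with an estimated correlation). The EGFR ligands EREG and TGFA, epiregulin and transforming growth factor alpha, fell 16.7-fold (13.7 to 20.2) and 6.27-fold (5.09 to 7.74). NRG1, the ligand of ERBB3, fell 1.71-fold and EGF 1.67-fold. The call of the list ended with the floor, as did that of EGF.

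**Figure D1:**
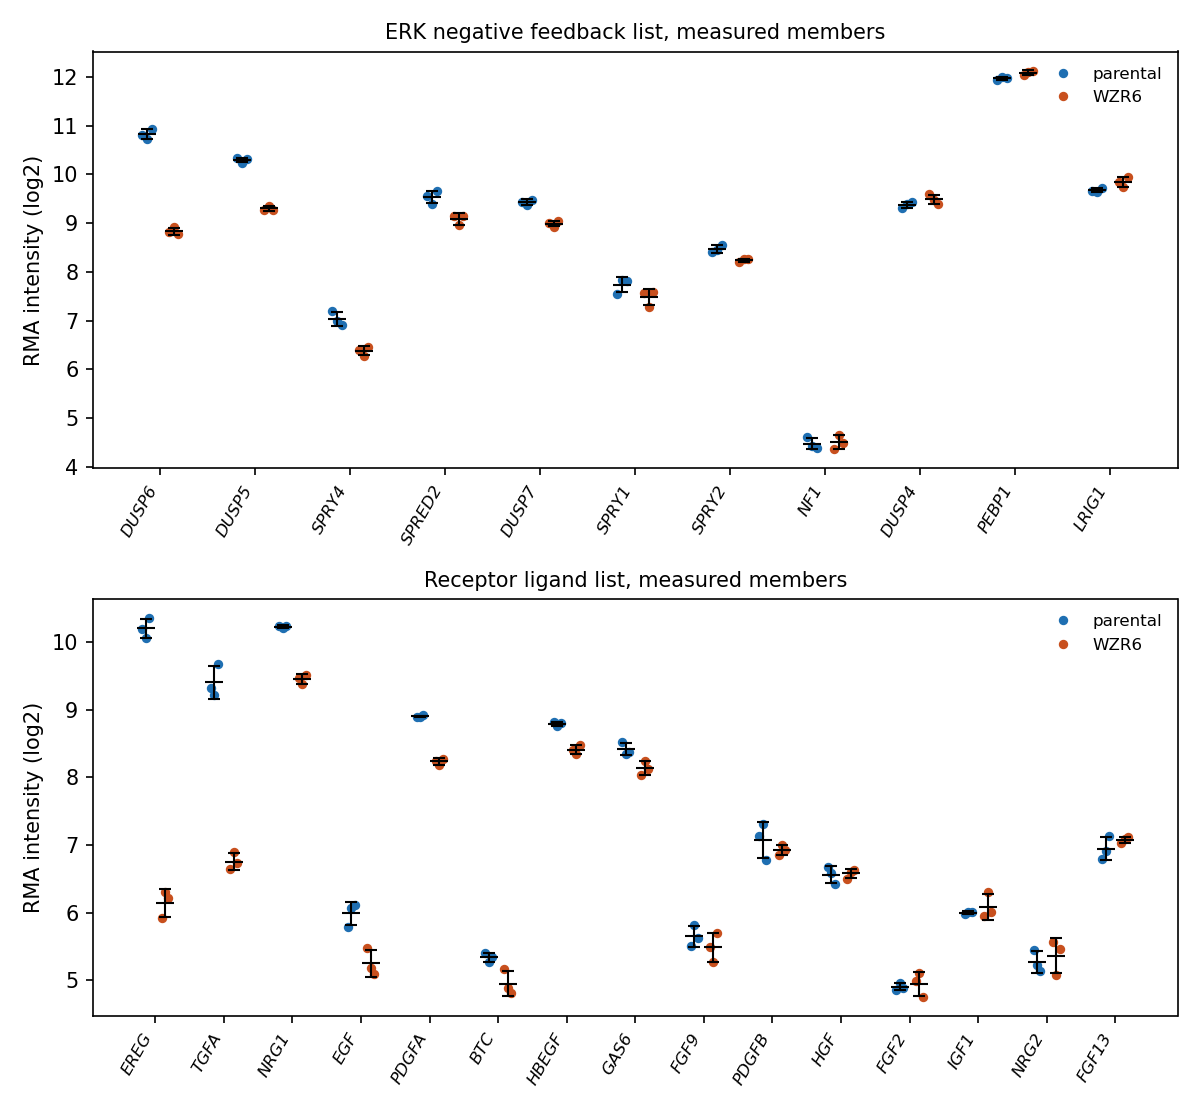
Log2 RMA intensity of the 11 measured ERK negative feedback genes (top) and the 15 measured receptor ligands (bottom) on each array, parental in blue and WZR6 in orange, with black bars for mean ± SD of 3 arrays. DUSP6 dropped from 10.83 to 8.83 and EREG from 10.20 to 6.14, while genes on the right of each panel overlapped or differed little.

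The epithelial list showed the most coherent change, as 18 of its 20 measured members fell and 2, KRT18 and OVOL1, were not called. Adjusted over the list alone, 19 fell. The median difference was -2.11 (camera adjusted p = 6.97e-12; adjusted p = 0.036 with an estimated correlation), and 13 members fell at least 2-fold. Beside EPCAM, CDH1 and ESRP1, the protease inhibitor SPINT2 fell 9.62-fold. The tight junction gene CLDN7 differed by -2.78 on the log2 scale, the transcription factor GRHL2 by -2.63 and the keratins KRT19 and KRT8 by -1.71 and -0.22, KRT8 within a run of 31 neighbouring genes with a median of -0.42. Among probe sets above the 75th percentile of level alone, which leaves out EPCAM and other members that WZR6 had nearly lost, the list was not called (median -0.49, adjusted p = 0.102).

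Mesenchymal genes did not shift as a list (median 0.15, adjusted p = 0.160), with 10 of 23 higher, 4 lower and 9 not called. TAGLN, an actin-binding protein, rose 2.85-fold, the transcriptional repressors SNAI2 and ZEB2 2.00-fold and 2.25-fold, and the matrix protein SPARC 1.81-fold. The call of ZEB2 ended with the floor, and TAGLN lies in a run of 48 neighbouring genes with a median of 0.41. VIM, the intermediate filament vimentin, differed by 0.08 ± 0.04 (SE, adjusted p = 0.167), and FN1, fibronectin, fell by 0.61 ± 0.07.

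**Figure D2:**
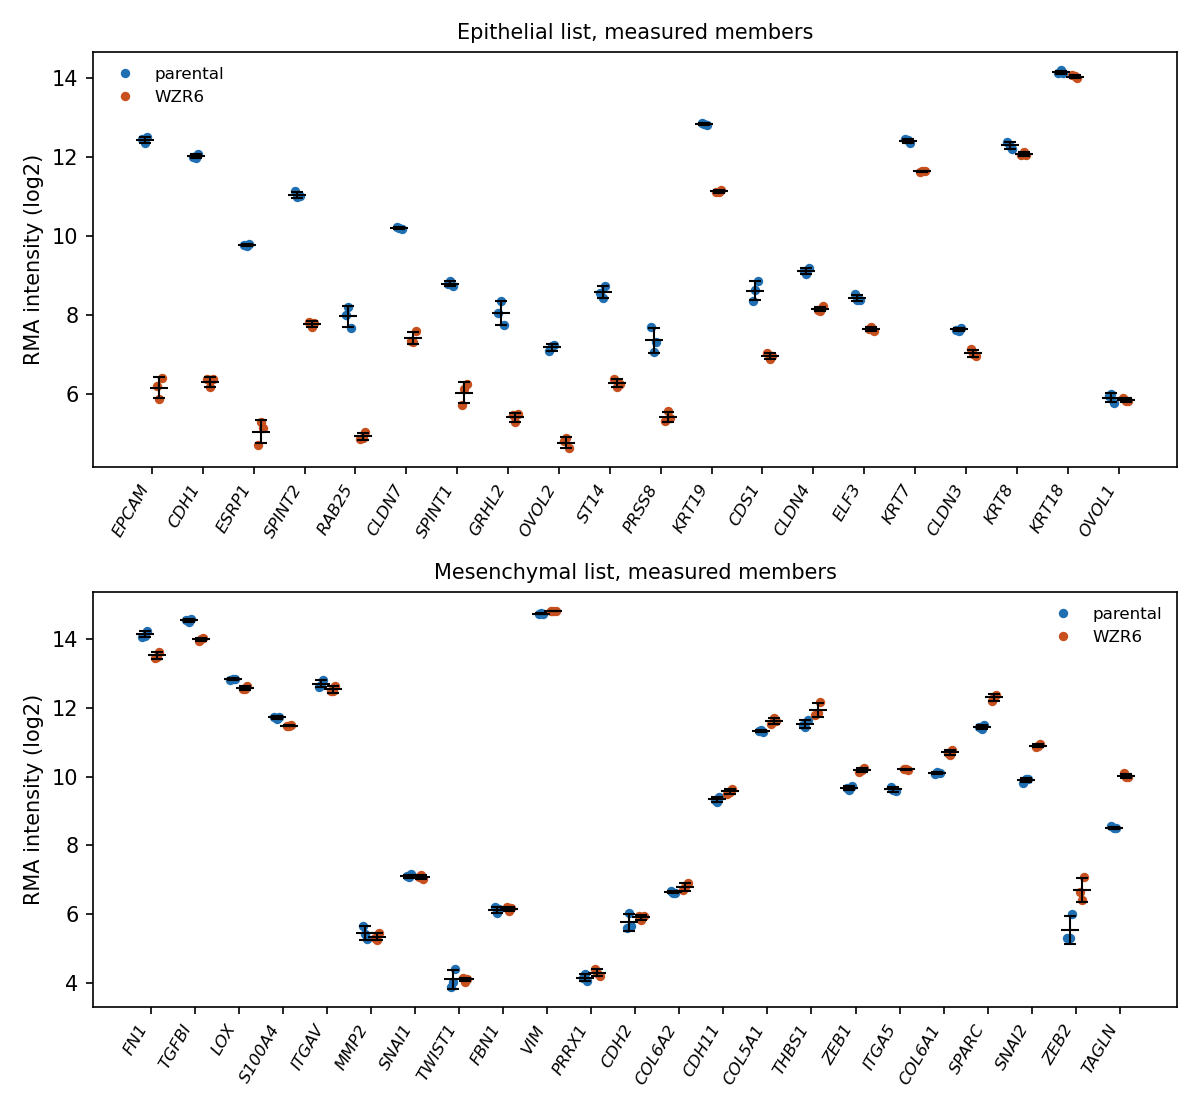
Log2 RMA intensity of the 20 measured epithelial genes (top) and the 23 measured mesenchymal genes (bottom) on each array, parental in blue and WZR6 in orange, with black bars for mean ± SD of 3 arrays. EPCAM dropped from 12.43 to 6.17 and CDH1 from 12.01 to 6.32, while 9 of the 23 mesenchymal genes, VIM among them, were not called and TAGLN rose from 8.52 to 10.03.

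Lung markers fell for 6 of 16 measured genes and 10 were not called (median -0.09, adjusted p = 0.0346; adjusted p = 0.248 with an estimated correlation). The lineage factors FOXA2 and NKX2-1 fell 6.30-fold and 4.40-fold, the mucin MUC1 5.22-fold and the lysosomal protein LAMP3 2.38-fold. The list was not called among probe sets above the median level, where its median was -0.62, without _x_at and _s_at probe sets, where it was -0.07, or with the floor. Drug transporters and drug-metabolizing enzymes fell for 9 of 16 genes, 2 rose and 5 were not called (median -0.24, adjusted p = 0.0246; adjusted p = 0.248 with an estimated correlation), and 10 fell when adjusted over the list alone. CYP24A1, the vitamin D hydroxylase, fell 8.42-fold, the exporter ABCC3 2.95-fold and the retinal dehydrogenase ALDH1A3 2.27-fold, while the exporter ABCB1 differed by -0.07 ± 0.06 (SE, adjusted p = 0.399), with both means below the lower quartile. ABCC3 lies in the same lowered run as GRB2. The call of the list ended with the floor, as did that of CYP24A1, and above the 75th percentile of level, where the median was -0.47.

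Both lists that rose were metabolic or stress programs. Cholesterol synthesis genes rose for 8 of 12, fell for 2 and were not called for 2 (median 0.50, adjusted p = 0.0246; adjusted p = 0.250 with an estimated correlation). SQLE, squalene epoxidase, rose 1.86-fold, the sterol sensor INSIG1 1.62-fold, the sterol-responsive factor SREBF2 1.49-fold and HMGCS1, which makes HMG-CoA, 1.48-fold. INSIG1 rose against a run of 44 neighbouring genes with a median of -0.38. Targets of ATF4 and of the unfolded protein response rose for 12 of 18, fell for 3 and were not called for 3 (median 0.27, adjusted p = 0.0320; adjusted p = 0.248 with an estimated correlation). The serine synthesis enzymes PHGDH and PSAT1 rose 2.19-fold and 2.07-fold and the stress factor ATF3 2.14-fold, while the lipoprotein receptor VLDLR fell 2.16-fold, a call that ended with the floor. Above the 75th percentile of level, with fewer genes tested, neither list was called although the medians were 0.49 and 0.27, and without _x_at and _s_at probe sets the ATF4 list was not called at a median of 0.24.

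The remaining lists were not called by camera, although single members changed strongly. Interferon response genes fell for 11 of 21, rose for 7 and were not called for 3 (adjusted p = 0.160). IFI27 fell 13.2-fold, OAS1 3.97-fold and the antiviral GTPase MX1 2.65-fold, while OASL rose by 0.94 ± 0.05 (SE). NF-kB targets and cytokines split into 9 higher, 10 lower and 2 not called, with the chemokines CCL5 and CCL2 higher by 4.81-fold and 2.26-fold and CXCL1 lower by 2.86-fold. Antigen presentation genes also split, with 10 of 16 higher, 5 lower and 1 not called (adjusted p = 0.256; called among probe sets above the median level, adjusted p = 0.0348, and above the 75th percentile, 0.0034). The MHC class II gene HLA-DPA1 and CD74, which encodes the class II invariant chain, fell 8.31-fold and 7.73-fold. The class I gene HLA-F rose 2.15-fold, in a run of 89 neighbouring genes with a median of 0.43. HLA-B, HLA-C, HLA-E, TAP1, TAP2, TAPBP, PSMB8 and PSMB9 also rose in that run, where HLA-DMA differed by -0.50. Most raised members thus lie in 1 stretch of neighbouring genes. Their count and the calls among brighter probe sets cannot be told apart from the shift of that run. Class I genes resemble each other closely, so their probe sets can cross-hybridise and HLA-F is uncertain. Among BCL2 family genes 6 of 14 rose, 3 fell and 5 were not called, and 7 rose when adjusted over the list alone. The prosurvival BCL2A1 fell 18.3-fold, to a mean of 4.60 that lay below the lower quartile, the prosurvival BCL2L1 fell 1.32-fold and the proapoptotic BAK1 rose 1.32-fold, in the same raised run as HLA-F. BCL2L11, the proapoptotic BIM, differed by -0.10 ± 0.10 (adjusted p = 0.468), and by -0.20 without parental replicate 1 (adjusted p = 0.0412).

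NRF2 targets fell for 7 of 16, rose for 4 and were not called for 5, and 9 fell when adjusted over the list alone (adjusted p = 0.0689). The heme-degrading HMOX1 fell 5.69-fold, the aldo-keto reductases AKR1B10 and AKR1C3 3.09-fold and 2.41-fold, and NQO1 1.76-fold. PI3K-AKT-mTOR components rose for 7 of 16, fell for 3 and were not called for 6; the phosphatase INPP4B rose 2.03-fold, PIK3CD 1.83-fold and MTOR 1.52-fold, and the insulin receptor substrate IRS1 fell 2.46-fold. PIK3CD and MTOR lie in 1 run of 98 neighbouring genes with a median of 0.46. Cell cycle genes rose for 7 of 25, fell for 10 and were not called for 8, and 12 fell when adjusted over the list alone. CDC20, a mitotic regulator, rose 2.02-fold, in a run of 128 neighbouring genes with a median of 0.49, and the replication genes MCM2 and CCNE1 fell 1.71-fold and 1.55-fold. YAP-TEAD targets rose for 6 of 14, fell for 3 and were not called for 5; ANKRD1, CCN1 and CCN2 rose 5.29-fold, 2.46-fold and 2.07-fold and NT5E fell 4.76-fold. CCN1 lies in the same raised run as CDC20, and CCN2 in a run of 31 genes with a median of 0.43. TGF-beta targets rose for 8 of 18, fell for 8 and were not called for 2. INHBA rose 20.2-fold against the lowered run that also holds EGFR, and PMEPA1 and LTBP2 fell 2.40-fold and 2.35-fold, LTBP2 within a run of 32 genes with a median of -0.39. WNT targets rose for 1 of 9, fell for 3 and were not called for 5, with the WNT inhibitor DKK1 lower by 4.18-fold. Glycolysis and hypoxia genes rose for 8 of 20, fell for 5 and were not called for 7, with EGLN3 higher by 1.67-fold and ANGPTL4 lower by 3.90-fold.

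Markers of other cell types gave no list call. Leukocyte markers fell for 2 of 12, ITGB2 2.58-fold and CD14 1.94-fold, and the other 10 were not called; the call of ITGB2 ended with the floor. Of 14 fibroblast and endothelial markers 10 were not called, POSTN and CDH5 rose, and COL1A1 and COL1A2 fell. COL1A1 is uncertain, since its 4 probe sets differed by -3.00, -1.27, 0.08 and 0.05, and COL1A2, lower by 1.47-fold, lies in the lowered run that holds EGFR. The call of CDH5 ended with the floor. Squamous markers fell for 5 of 12, rose for 1 and were not called for 6 (adjusted p = 0.0563), with S100A2 lower by 4.32-fold and KRT15 by 2.50-fold. That list was called in 5 alternatives, with adjusted p-values down to 0.0198. Neuroendocrine markers rose for 1 of 12, fell for 3, among them UCHL1 by 1.66-fold, and were not called for 8. Housekeeping genes rose for 5 of 11, fell for 3 and were not called for 3, with differences between -0.46 for GUSB and 0.38 for IPO8. GUSB and PPIA, lower by 1.37-fold and 1.21-fold, lie in the lowered run that holds EGFR, and the call of IPO8 ended with cyclic loess.

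**Figure D3:**
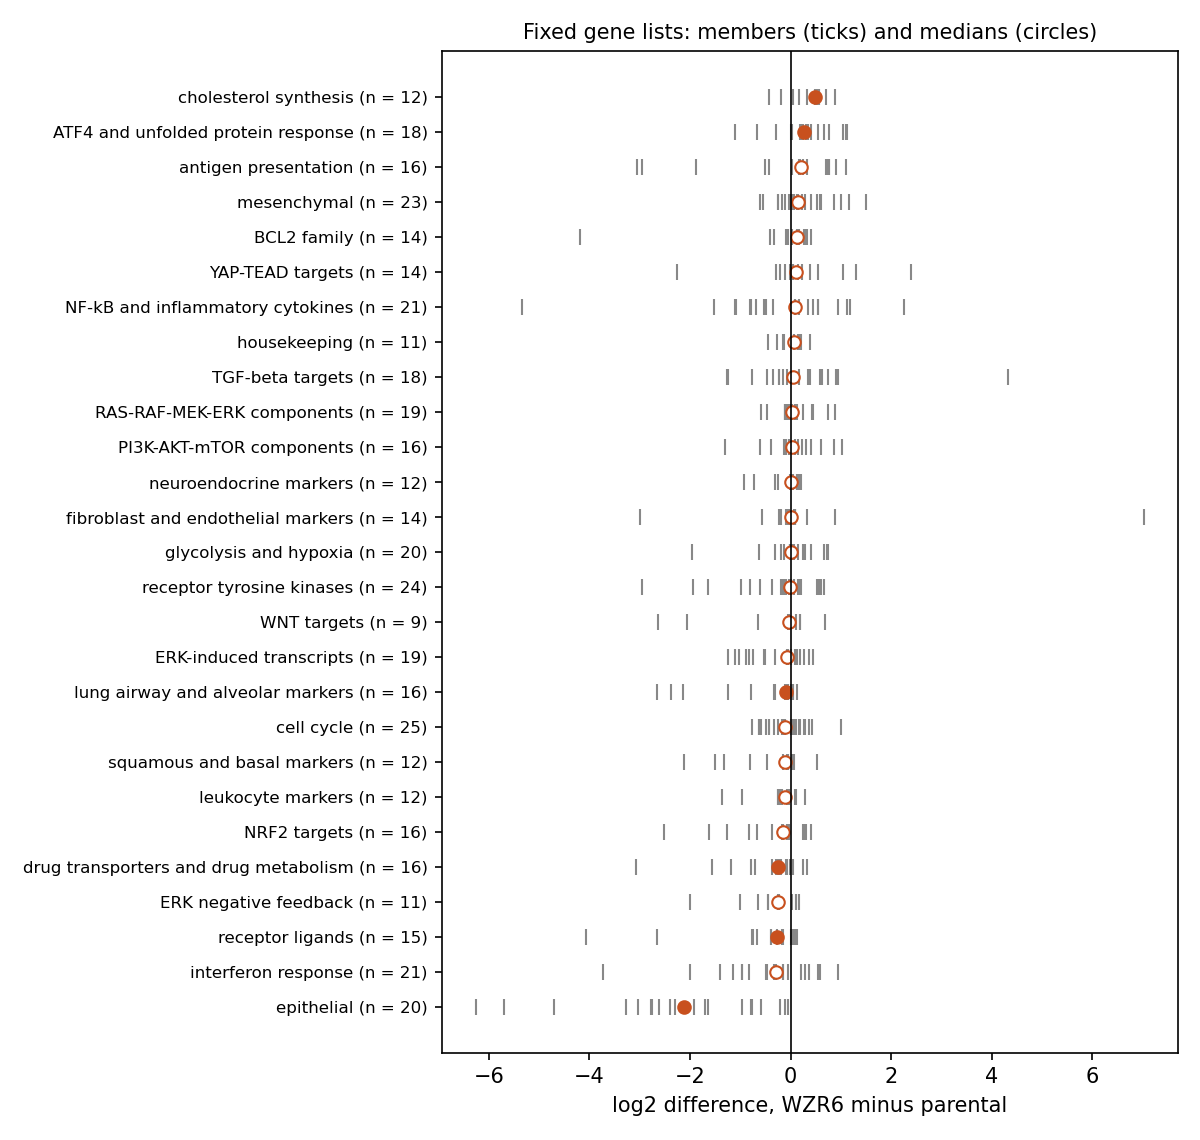
Log2 difference, WZR6 minus parental, of each measured member (grey ticks) of the 27 fixed gene lists, with the list median as a circle, filled where the camera adjusted p was under 0.05. The epithelial median, -2.11, stands apart from all other list medians, which lie between -0.28 and 0.50.

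Of 27 lists 6 were called by camera, 2 higher and 4 lower, and with an estimated correlation the epithelial list alone held. For all called lists but cholesterol synthesis (0.03) that estimate lay below the preset of 0.01, at -0.061 to -0.003. Correlation among members therefore does not account for the calls lost among those lists. The adjusted p of the epithelial list, with an estimate of -0.01, rose as well, from 6.97e-12 to 0.036. Adjusted over the list alone, counts of changed members were the same in 22 lists and differed in the 5 for which both are given. By fry, 25 lists moved on balance in 1 direction and 27 changed in either, which does not compare a list with other genes. Median, mean and test differed in sign for the BCL2, NF-kB, antigen presentation, neuroendocrine and fibroblast lists, and for housekeeping genes fry pointed lower and camera higher.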

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

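The tests on RNA quality and on fibroblast transcripts below were chosen only after the results they bear on were seen. The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, called 9131 probe sets, 5748 genes and 6 lists, and the highest counts of the other splits were 0, 0 and 2. Groups of 3 arrays were not tested for single samples that stand apart.

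Among the 62 control probe sets, which were left out of the probe set and gene tests, 1 was called higher in WZR6 and 2 were called lower. AFFX-M27830_M_at, which detects ribosomal RNA, differed by 0.30 (limma adjusted p = 0.0425 over the controls), and its sibling probe sets by 0.18 and 0.10 without a call. It was higher under each of the 3 scalings and called under median centring and quantile normalization, but not under cyclic loess (adjusted p = 0.0532). The 2 lower ones detect the interferon signaling factor ISGF3A. AFFX-HUMISGF3A/M97935_3_at differed by -0.41 (adjusted p = 0.00511) and was called under each of the 3 scalings, and AFFX-HUMISGF3A/M97935_MB_at differed by -0.33 (adjusted p = 0.0461), lower under each scaling but called under quantile normalization alone. Control probe sets for dap, lys, phe and thr were not called but leaned upward in WZR6, by up to 0.30. Only AFFX-r2-Bs-lys-M_at (-0.04) and AFFX-r2-Bs-phe-5_at (-0.03) among them were lower.

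More genes fell than rose by at least 2-fold, 409 against 163. If dim genes near background were the whole cause, the excess would be absent among brighter genes, yet above the median gene 174 fell and 97 rose, or 64.2% lower (exact binomial interval 58.2 to 69.9, which treats genes as independent). The share was 78.1% among dimmer genes, so background may still add to it. As a check on RNA degradation, the ratios of 3′ to 5′ control signal overlapped between the groups and showed no consistent rise in WZR6. That of GAPDH was at most 1.32 in WZR6 and between 1.27 and 1.40 in parental cells. That of ACTB was 3.54 to 3.85 in WZR6 and 2.82 to 3.76 in parental cells. With 3 arrays per group these ratios cannot exclude some degradation in WZR6. A change in the clone's own expression stays open as well.

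Epithelial genes fell while POSTN, a transcript abundant in fibroblasts, rose 131-fold. Fibroblasts among WZR6 cells would bring their other abundant transcripts too. Of 7 such transcripts, 5 had parental means below the median of all values (COL3A1, DCN, LUM, FAP and THY1), limma called none of them at an adjusted or unadjusted p under 0.05, and the highest upper bound of their differences was 0.75 on the log2 scale, for LUM. This argues against fibroblasts as the source of the POSTN increase. A shift of the clone itself toward a less epithelial state may account for the pattern, a hypothesis found and examined on the same 6 arrays, and the POSTN call rests on 1 of its 2 probe sets.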

How the results depend on the processing

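The alternatives were planned, but the rule that keeps each gene's probe set when an array is left out was set after the data were seen. Of 1869 results of the 127 named genes under alternatives, 1829 kept direction and side of the threshold. Leaving out each array in turn gave 7759 to 8415 probe sets (4002 to 4403 higher, 3757 to 4060 lower) and 5043 to 5441 genes, with 155 to 170 genes higher and 398 to 429 lower by 2-fold, 2 lists higher, 4 to 5 lower and a median of the ERK feedback list between -0.34 and -0.22. Above the median level, 329 probe sets and 237 genes were lower by 2-fold; the 75th percentile gave 4275 probe sets (2271 higher, 2004 lower, 59 and 123 by 2-fold), 2973 genes (1556 higher, 1417 lower, 42 and 100 by 2-fold) and 1 list higher and 0 lower, with fewer genes tested in both. The floor gave 331 probe sets and 245 genes lower by 2-fold and 1 list lower, and 21 of 124 called named genes were no longer called; all of these but CCNE2, whose difference stayed at -0.62 (adjusted p = 0.0722), had values under the floor, which became equal. Without _x_at and _s_at probe sets 8369 genes were left, 3487 called (1795 higher, 1692 lower, 105 higher by 2-fold) and 1 list was higher; the ERK feedback list was then called (-0.35, adjusted p = 0.0121, against 0.0121 to 0.568 over its alternatives), and the cause was not tested. With an estimated correlation 0 lists were higher and 1 lower. Directions reversed for MERTK (0.11) and DKK3 (0.040) without _x_at and _s_at probe sets, where another probe set stands for the gene, and for the uncalled NF1 without parental replicate 3 (-0.011) and without WZR6 replicate 2 (-0.043; range without each array -0.043 to 0.097), where the cause was not tested. The 2-fold gene calls were 65.8% to 74.3% lower over all alternatives. As a replicate block, the numbers changed no call of a named gene or list. They gave 9029 probe sets, 5729 genes, 2 lists higher and 4 lower, and the median of the ERK feedback list stayed at -0.26. Same-numbered arrays deviated with correlations of -0.01, 0.12 and 0.23, and arrays with different numbers with -0.24 to 0.13. These few overlapping values leave open whether the numbers pair the samples. Arrays without detection calls leave signal over background unknown for dim genes. IPO8, CCNE2, CHGB, ERBB3, MERTK and DKK3 were not called in more than 1 alternative; IPO8 did so without parental replicate 1, parental replicate 2, WZR6 replicate 2 or WZR6 replicate 3 (0.27 to 0.40), and CCNE2 without parental replicate 1 or WZR6 replicate 2 (-0.61 and -0.55).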

Other observations

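The tests of metallothioneins and other families and of dimmer genes inside runs were chosen only after the results they follow were seen, and the scan of neighbouring genes was run with 1 window size.

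Metallothioneins, small proteins that bind zinc and copper, were lower in WZR6. Of 10 measured members 9 fell, 8 of them at least 2-fold, and MT3 differed by -0.01 ± 0.10 (SE). MT1M fell 6.67-fold, MT1E 5.99-fold, MT1F 2.96-fold and MT2A 2.14-fold. The median of the family was -1.25, and it lay between -1.27 and -1.20, with 9 members lower, under cyclic loess, median centring and quantile normalization. The arrays were already alike in scale, with log2 medians of 7.34 to 7.41, so these scalings could change the family median little. Of 223 groups of at least 8 genes that share a symbol stem, this family alone was called by camera (adjusted p = 1.56e-05). It was not called with an estimated correlation (adjusted p = 0.999), although that estimate, -0.09, lay below the preset of 0.01. Members have near-identical sequences and probe sets can detect several of them, so single members are uncertain. For the same reason the 9 lowered members may hold fewer separate changes, and the camera p-value at the preset correlation may be too small.

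Genes that lie next to each other shifted together. The 5981 genes above the median level that could be placed were ordered as in GRCh38.p14, and medians of 25 neighbours were set against 1000 shuffled orders. Beyond the limit of 0.42 lay 569 of 5429 windows, in 18 runs, 7 higher and 11 lower, that held 1063 genes (17.8%). Run medians corresponded to 1.30-fold to 1.46-fold. The run with most genes reached from PDGFA to CLDN15, with 95.4% of 174 genes lower, and held EGFR, while INHBA rose within it. Next came FOXJ3 to DPH5, with 128 genes and a median of 0.49, and NOC2L to STMN1, with 98 genes and a median of 0.46.

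A candidate explanation is a difference in DNA copy number between the clone and parental cells. Dimmer genes, at or below the median level, took no part in the scan and should then shift with the run they lie in. In 16 of 18 runs the median of these genes lay on the run's side of 0.027, the median of dimmer genes outside runs. An exact binomial test gave a two-sided p of 0.00131, but it treats runs as independent, and several lie on 1 chromosome. In the lowered runs that start at MYOF, MCRS1 and UBE2Z the dimmer median was 0.020, 0.003 and 0.008, below that reference but not negative. The shift along the run was small, with a median of 0.05 over 1014 genes. Runs made of related genes alone were argued against, since 12 runs stayed beyond the then higher limit of 0.47 with 1 gene kept per symbol stem. Broad domains of shared regulation would give the same values and were not separated from copy number, because DNA was not analysed here.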
